A study of Mus musculus with 103 samples.

How the data were processed

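The series holds 103 samples of craniofacial tissue from CD1 mouse embryos at E8.5, E9.5 and E10.5. Per the labels' protocols, embryos were flash frozen and cryosectioned, regions were captured with an Arcturus Veritas laser microdissection instrument, RNA was isolated with a Zymo kit, amplified with the NuGEN Ovation Pico WTA system, labelled with biotin and hybridised to Affymetrix whole-transcript arrays. The submitters' processing notes name RMA, with no version, and genome build mm9.

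The table deposited by the authors gives a linear ratio for each probe set and sample. Tested on the table, the median of every probe set over 1 set of 21 samples was 1 within 6e-08, which a division of each probe set by that median would give. The labels do not describe such a step, so the baseline is known from the values alone. The smallest ratio was 0.01, which 62 values shared and which appears to be a lower bound, and the largest was 144. Of 35557 probe sets, 6701 had no value in any sample. No background level or detection call was used, so that weak and strong genes cannot be told by their values. The planned design had assumed log2 levels. The log2 of each ratio was used in its place, and the planned filter on dim genes was not run, because a mean ratio is not a level.

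Of the 28856 probe sets with values, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 5446 had none. Only the first were used. Symbols of 21698 were found by Entrez identifier in a current gene table, where 0 had been renamed, and 91 kept the annotation's symbol. For 999 genes with several probe sets, the one with the highest mean log2 ratio was used, and 19938 genes were tested. Genome coordinates are not given because the build of the gene table differs from mm9.

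Samples were grouped by their labels into 22 groups. An E9.5 sample whose title and source name say mandibular arch, while its description and tissue label say epidermal ectoderm, was left out. For 4 E10.5 neuroepithelium samples the title names the lateral and the other labels the medial prominence, and they were grouped as medial. Samples are not tied to embryos in the labels. Libraries of 1 group may therefore share an embryo, and the p-values, which treat each sample as a replicate, may be too small.

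Group means were fitted over 102 samples with limma 3.58.1 in R 4.3.3, which left 80 residual degrees of freedom, and 16 comparisons and 2 differences of comparisons were tested as contrasts with eBayes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. A gene was called enriched in a region where it was 2-fold or more higher and passed against each other region of its stage. For 32 gene lists with 407 entries and 356 different genes, fry tested whether members moved 1 way on balance, with adjustment over the 512 pairs of list and comparison. The lists cover neural, mesenchymal, arch, ectodermal, placodal, signalling, muscle, endodermal, cardiac, blood, vessel, macrophage, cell cycle, stress and hypoxia genes.

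The groups, tests, lists, alternatives and the rule for genes to be named were fixed before the data were examined. By that rule, in each comparison, up to 6 called genes of each direction with the largest differences and no overlap between libraries, predicted genes, olfactory and vomeronasal receptors and small RNAs passed over, and up to 3 called members, or the 1 largest, of each list set beside the comparison, were taken. For differences of comparisons and for regions the 3 largest were taken. Members of other lists that moved were named after their values were seen, and some genes the rule takes, among them genes whose calls an alternative ended, are left out for length, also after their values were seen.

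The alternatives fixed with them were quantile normalization, array weights, a variance trend with robust prior, the mean of all probe sets of a gene, a fit of the compared groups alone, the same with the replicate number as a block, each library left out in turn, other placements of the samples with conflicting labels, and camera with a preset correlation of 0.01 or an estimated one. Added after the data were seen were the omission of 11 arrays whose log2 ratios had an SD over 0.85, a limit chosen after counts with and without these arrays were known, the 5th percentile of each array as a covariate, the mean of 2 similar arrays, maxillary arch ectoderm alone as reference for the olfactory pit and Rathke's pouch, otic libraries 3 and 5 left out, lateral and control neuroepithelium alone with and without the block, and fry with each library left out, without the widely spread arrays and with the covariate.

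In simulated data 200 of 19938 genes were changed. For the floor plate, arches and cranial mesenchyme, arch ectoderm and mandibular stage comparisons, 65%, 66%, 59% and 62% of 2-fold and 87%, 90%, 79% and 83% of 4-fold changes were recovered, and 6.17%, 2.5%, 3.5% and 5.23% of calls were unchanged genes. For regions, 94% of genes raised 8-fold in E8.5 mesenchyme were recovered. These shares hold for the simulated data and need not hold for arrays of unlike spread. Tables used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.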

Results

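The atlas measured gene expression in the developing face of outbred CD1 mouse embryos at embryonic days E8.5, E9.5 and E10.5. Regions were laser-captured, with 1 whole-transcript array per sample. The labels put all samples but 1 into 22 groups of 4 to 7 libraries: 4 regions at E8.5 (18 libraries), 6 at E9.5 (34) and 12 at E10.5 (50). The other E9.5 sample, with conflicting labels, entered no comparison. Values are log2 ratios to the authors' baseline, which compare libraries for 1 gene but give no level between genes. The number of arrays per group limits the precision. Libraries may share an embryo, which would make each p-value below too small. SE and p use a spread pooled over 22 groups and may be too small where the compared groups spread more. Means are given ± SD with n, differences ± SE, and adjusted p is limma's Benjamini-Hochberg value. For genes with a probe set number, no library of one side overlapped the other unless stated, partly because the naming rule asks it. Among all genes, non-overlap was rarer than by chance in the E9.5 arches (0.502% against 0.794%) and under the prominences, and more common elsewhere.

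At E8.5, neural epithelium was captured along the floor plate, the ventral midline strip, and outside it, which asks what marks the ventral midline. Nkx2-9 (probe set 10400479), a homeobox gene of the ventral neural tube, was 29.6-fold higher in floor plate, at 4.78 ± 0.55 (SD, n = 4) against -0.10 ± 0.87 (SD, n = 5), a difference of 4.89 ± 0.57 (SE, adjusted p = 4.9e-09). Aldh1a2 (probe set 10586865), an enzyme that makes retinoic acid, was 7.89-fold lower in floor plate, at 1.48 ± 0.89 (SD, n = 4) against 4.46 ± 0.60 (SD, n = 5), a difference of -2.98 ± 0.21 (SE, adjusted p = 7.1e-20). Tac1, a neuropeptide precursor, was 22-fold lower (adjusted p = 3.4e-05). In all, 18 genes rose and 18 fell.

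Of 11 measured floor plate genes, 3 rose and 8 did not pass, with 4 higher when adjusted over the list alone. Beside Nkx2-9 these were Foxa2, a transcription factor that specifies floor plate, at 5.26-fold (adjusted p = 0.018), and Nkx2-2, a ventral homeobox gene, at 2.62-fold (adjusted p = 0.0049). The list moved up (fry adjusted p = 0.00835), but not after quantile normalization (adjusted p = 0.0757) or without floor plate replicate 4 (adjusted p = 0.0525). Foxa2 did not pass without floor plate replicate 3 (1.88, adjusted p = 0.16) or 4 (1.79, adjusted p = 0.27), and Nkx2-2 did not pass without floor plate replicate 1 (0.94, adjusted p = 0.14) or after quantile normalization (1.30, adjusted p = 0.088). The retinoic acid list moved down (adjusted p = 0.00398), with Aldh1a2 as the member of 11 that fell, also 1 adjusted over the list alone. The lists of Hedgehog response, neural epithelium and mesenchyme genes did not move (adjusted p = 0.319 to 0.818), and Lum, a mesenchyme gene, was at 0.94, or -0.10 without floor plate replicate 4. That library stood apart in lists of other tissues, with means of 0.32 for mesenchyme, 1.08 for surface ectoderm, 1.12 for BMP, 1.06 for mandibular and 0.68 for Hedgehog response genes, against -0.86 to -0.54, -0.19 to 0.19, -0.61 to -0.50, -0.35 to -0.11 and -0.09 to -0.03 in the other 3. With array weights 99 genes passed, and with the compared groups fitted alone 1 gene, none of the 36. Without floor plate replicates 1, 2, 3 and 4 in turn, 67, 69, 78 and 58 genes passed.

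E8.5 mesenchyme, the loose tissue under the epithelia, was compared with the mean of the 3 neural epithelium groups. Foxc2 (probe set 10576051), a forkhead gene of head and paraxial mesenchyme, was 26.3-fold higher in mesenchyme, at 4.56 ± 0.25 (SD, n = 5) against -0.16 ± 0.65 (SD, n = 13), a difference of 4.72 ± 0.56 (SE, adjusted p = 1.1e-09). Hapln1 (probe set 10406519), a link protein of the extracellular matrix, was 21.2-fold higher (4.40 ± 0.38, adjusted p = 2.3e-15). Fgf15 (probe set 10559373), a growth factor of neural tissue, was 5.87-fold lower (-2.55 ± 0.36, adjusted p = 1.5e-07). In all, 328 genes rose and 150 fell, and with array weights 896 passed.

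Of 15 measured mesenchyme genes, 12 rose and 3 did not pass, and 14 were higher when adjusted over the list alone (fry adjusted p = 5.16e-17). Foxc1 was 18.5-fold and Lum, a collagen-binding proteoglycan, 20.6-fold higher. Of 9 neural crest genes 5 rose, 6 adjusted over the list alone (fry adjusted p = 6.52e-11). Sox10, a regulator of crest cells, was 3.2-fold higher with overlapping libraries (adjusted p = 0.00011). Endothelial genes moved with mesenchyme: 9 of 10 rose, 10 adjusted over the list alone (fry adjusted p = 1.49e-16), among them Emcn (probe set 10496359), a vessel surface sialomucin, at 25.5-fold (4.67 ± 0.75, adjusted p = 4.8e-06) and Cldn5, a tight junction protein of vessels, at 23.0-fold (adjusted p = 4.6e-12). Of 8 erythroid genes 3 rose, 4 adjusted over the list alone (fry adjusted p = 0.00975). These were embryonic globins with overlapping libraries, Hba-x at 4.14-fold, and Hbb-bh1 and Hbb-y, for which no fold is given because 9 and 10 of the 18 E8.5 libraries lay at the smallest ratio. After quantile normalization the erythroid list (adjusted p = 0.186) and the globins did not pass, nor did the globins without mesenchyme replicate 3 (1.63, 1.25 and 1.25 on the log2 scale) or the list without mesenchyme replicate 3 or 5 (adjusted p = 0.0975 and 0.0802). Hbb-bh1 (2.00, adjusted p = 0.084) and Hba-x (1.38, adjusted p = 0.15) did not pass without mesenchyme replicate 5.

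The frontonasal (fry adjusted p = 7.29e-08) and BMP lists (fry adjusted p = 0.00144) also moved up in mesenchyme. Of 8 frontonasal genes 4 rose, 5 adjusted over the list alone. Of 13 BMP genes 3 rose, 4 adjusted over the list alone. The immediate early list moved up (adjusted p = 0.028, adjusted p = 0.066 with an estimated correlation), with 1 of 9 higher, Atf3 by 1.51, also 1 adjusted over the list alone, but not without mesenchyme replicate 2 or 5 (adjusted p = 0.0929 and 0.142). Of 15 neural epithelium genes 1 fell, with 1 higher and 5 lower adjusted over the list alone, and the list did not move (fry adjusted p = 0.069). The gene was Pax6, a homeobox gene of neural tube and eye (adjusted p = 0.019), but not without mesenchyme replicate 2, 3 or 5 (adjusted p = 0.14, 0.11 and 0.12). Forebrain and midbrain regulators moved down (fry adjusted p = 6.4e-05), with 5 of 11 lower, 7 adjusted over the list alone, as did FGF genes (adjusted p = 0.00229), with 2 of 14 lower, 4 adjusted over the list alone. The boundary list of midbrain and hindbrain moved down (adjusted p = 0.0107, adjusted p = 0.066 with an estimated correlation, adjusted p = 0.0832 after quantile normalization), with 1 of 9 lower, 6 adjusted over the list alone. The arch muscle list did not move (adjusted p = 0.667).

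Caudal neural epithelium at E8.5 was compared with non-floor plate neural epithelium, to ask what differs along the head to tail axis. Fezf1 (probe set 10543362), a zinc finger gene of the forebrain, was 55.6-fold lower in caudal libraries, at -0.33 ± 0.05 (SD, n = 4) against 5.47 ± 0.33 (SD, n = 5), a difference of -5.80 ± 0.75 (SE, adjusted p = 3.1e-08). Hesx1 (probe set 10413393), a homeobox gene of forebrain and pituitary, was 46.1-fold lower (-5.53 ± 0.57, adjusted p = 6.7e-12). Pax6 was 34.0-fold lower (adjusted p = 1.7e-07) and Aldh1a2 was 16.6-fold lower (adjusted p = 2.3e-28). Cldn10 (probe set 10417027), a claudin, was 25.4-fold higher (4.66 ± 0.84, adjusted p = 0.00012). Hes3, a repressor that keeps progenitors undifferentiated, was 16.9-fold higher (adjusted p = 1.8e-10). In all, 235 genes rose and 48 fell, and after quantile normalization 94 rose and 65 fell.

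Of 11 forebrain and midbrain regulators 6 fell and 5 did not pass, 7 adjusted over the list alone (fry adjusted p = 5.87e-09). Of 9 midbrain-hindbrain boundary genes 7 rose (fry adjusted p = 9.85e-15), also 7 adjusted over the list alone. Pax8, a paired box gene of that boundary, was 11.6-fold higher (adjusted p = 2.4e-15). FGF genes moved up (fry adjusted p = 3.87e-05) with 7 of 14 higher, 8 adjusted over the list alone, among them Fgf18 by 2.63. WNT genes moved up too (adjusted p = 0.00261, but adjusted p = 0.115 after quantile normalization), with 5 of 20 higher and 1 lower, 6 and 1 adjusted over the list alone. The olfactory placode (fry adjusted p = 5.33e-07) and pituitary placode lists (adjusted p = 4.6e-05) moved down with 5 of 11 and 2 of 11 members lower, 5 and 3 adjusted over each list alone. Surface ectoderm genes had means of 0.71, 0.77 and 0.56 in non-floor plate replicates 1 to 3, -0.05 and -0.11 in replicates 4 and 5 and -0.36 to -0.13 in caudal libraries, and the list did not pass (adjusted p = 0.196). Retinoic acid genes moved down (adjusted p = 0.00422, adjusted p = 0.107 with an estimated correlation), with 1 of 11 lower, Aldh1a2, and 1 higher, 1 and 2 adjusted over the list alone. The 25 Hox genes, which pattern the trunk and hindbrain, did not move (adjusted p = 0.807). The caudal progenitor list did not move either (adjusted p = 0.365), with 2 of 9 higher, also 2 adjusted over the list alone. Array weights gave 714 genes and the compared groups alone 76.

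**Figure D1:**
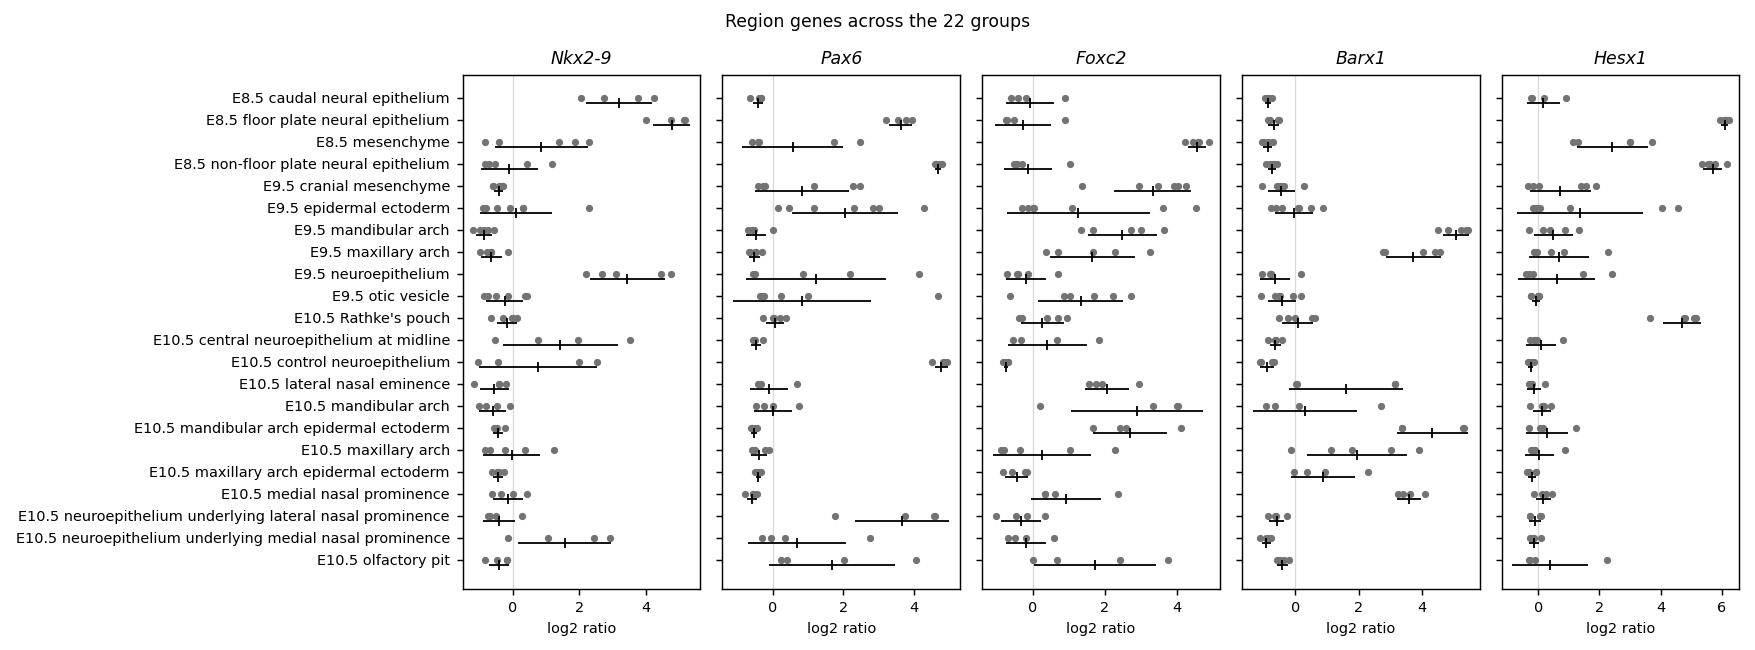
Log2 ratio (x axis) of Nkx2-9, Pax6, Foxc2, Barx1 and Hesx1 in the 22 groups (y axis), where points are libraries and the tick and bar are the mean ± SD. The E8.5 floor plate libraries average 4.78 for Nkx2-9, the E8.5 mesenchyme libraries 4.56 for Foxc2, and the 5 Rathke's pouch libraries 4.69 for Hesx1.

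At E9.5, the maxillary and mandibular arches, which form the upper and lower jaw, were compared together with cranial mesenchyme. Barx1 (probe set 10404982), a homeobox gene of arch mesenchyme, was 28.6-fold higher in the arches, at 4.40 ± 0.95 (SD, n = 10) against -0.44 ± 0.42 (SD, n = 6), a difference of 4.84 ± 0.39 (SE, adjusted p = 2.1e-16). Six2 (probe set 10453394), a homeobox gene of head mesenchyme, was 9.28-fold lower in the arches (-3.21 ± 0.43, adjusted p = 3e-07). Pax3, a paired box gene of neural crest, was 3.16-fold lower (adjusted p = 0.0001). In all, 148 genes rose and 38 fell, and after quantile normalization 137 rose and 80 fell.

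Of 13 pharyngeal arch genes 6 rose and 7 did not pass, 8 adjusted over the list alone (fry adjusted p = 6.36e-11). Dlx5, a homeobox gene of the lower jaw, was 19.2-fold higher with overlapping libraries (adjusted p = 7.8e-06). Lhx8, a LIM homeobox gene of oral mesenchyme, was 9.92-fold higher (adjusted p = 0.00023). The mandibular list moved up as well (fry adjusted p = 2.25e-07) with 5 of 8 higher, also 5 adjusted over the list alone. Frontonasal regulators moved down (fry adjusted p = 9.85e-15) with 4 of 8 lower, 5 adjusted over the list alone, among them Alx1, a homeobox gene of frontonasal mesenchyme, at 10.4-fold, and Tfap2b, a crest transcription factor, at 5.61-fold, both with overlapping libraries. The neural epithelium list moved down (adjusted p = 0.0095) with 2 of 15 members lower when adjusted over the list alone. Arch muscle genes moved up (adjusted p = 0.00238, adjusted p = 0.142 with an estimated correlation, adjusted p = 0.204 after quantile normalization), with 1 of 10 higher, Msc, a muscle precursor gene, at 2.84-fold, and 3 higher adjusted over the list alone. The neural crest (adjusted p = 0.0919) and endothelial lists (adjusted p = 0.069) did not move. Of 9 neural crest genes 1 fell, Tfap2b, 2 adjusted over the list alone, with 4 of 10 endothelial genes higher adjusted over the list alone and Emcn at 1.5, or 2.07 with array weights (adjusted p = 0.018). With array weights 3495 genes passed, and with the compared groups alone 12. Without cranial mesenchyme replicates 1, 2, 4, 5 and 6 the counts were 81, 927, 92, 82 and 85, without mandibular arch replicates 2, 3, 4 and 5 they were 80, 303, 381 and 88, and without maxillary arch replicates 1 to 5 they were 89, 80, 114, 568 and 485.

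The mandibular and maxillary arches at E9.5 differed in 14 genes. Hand2 (probe set 10571860), a transcription factor of the lower jaw, was 5.62-fold higher in the mandibular arch, at 2.41 ± 1.02 (SD, n = 5) against -0.07 ± 0.72 (SD, n = 5), a difference of 2.49 ± 0.32 (SE, adjusted p = 2.6e-07). Pitx1 (probe set 10409551), a homeobox gene of the lower jaw and oral ectoderm, was 11.1-fold higher (3.48 ± 0.69, adjusted p = 0.0084), and did not pass without mandibular arch replicate 3 (3.07, adjusted p = 0.072). Of 8 mandibular genes, targets of endothelin signalling, 3 rose and 5 did not pass, 6 adjusted over the list alone (fry adjusted p = 6e-08). The pharyngeal arch list moved up too (fry adjusted p = 0.000618), with 2 of 13 higher, 5 adjusted over the list alone. The maxillary, arch muscle, BMP and surface ectoderm lists did not move (adjusted p = 0.626 to 0.975), and Cldn6, an epithelial claudin, was at -0.52, or at 0.06 with the further E9.5 sample counted as mandibular arch.

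Of these genes 12 rose and 2 fell, and after quantile normalization all 5 that passed were higher. Array weights gave 85 genes (16 rose, 69 fell), the further sample as mandibular arch 7 and the compared groups alone 0 in limma. In the fit over all groups 692 genes had an unadjusted p under 0.05, fewer than chance alone gives. Without mandibular arch replicates 2 and 3 the counts were 4 and 9, and without maxillary arch replicates 1, 2 and 5 they were 23, 7 and 23.

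The E9.5 otic vesicle, the future inner ear, was compared with epidermal ectoderm. Pitx1 was 26.7-fold lower in the otic vesicle, at 0.11 ± 0.65 (SD, n = 6) against 4.84 ± 0.72 (SD, n = 7), a difference of -4.74 ± 0.60 (SE, adjusted p = 1.5e-07). Aldh1a3 (probe set 10564417), an enzyme that makes retinoic acid, was 10.8-fold lower (-3.44 ± 0.35, adjusted p = 3.9e-11). In all, 62 genes rose and 16 fell, and after quantile normalization 44 rose and 22 fell. Of 12 otic genes 4 rose and 8 did not pass, 6 adjusted over the list alone (fry adjusted p = 0.000409), by 0.69 on average, or 0.42 without otic replicate 4 (adjusted p = 0.00812). The otic list mean was 1.21 to 2.56 in 4 of the 6 libraries, but 0.27 in replicate 3 and -0.26 in replicate 5, where the forebrain and midbrain list was 1.31 and 1.81, against -0.42 to 0.16 in the 4. Without these 2 libraries 168 genes rose and 22 fell, and the FGF list moved up (adjusted p = 0.00367).

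Pituitary placode genes moved down in the otic vesicle (fry adjusted p = 1.17e-05) with 2 of 11 lower, 4 adjusted over the list alone. Beside Pitx1 this was Isl1, a LIM homeobox gene of sensory and placodal cells, at 7.63-fold lower (adjusted p = 0.018), which did not pass without ectoderm replicate 1 (-2.66, adjusted p = 0.051) or 2 (-2.67, adjusted p = 0.06). The lists of surface ectoderm, neuronal differentiation and FGF genes did not move (adjusted p = 0.178 to 0.589), although 1 of 20 neuronal genes, Isl1, fell, and 3 of 14 FGF genes were higher adjusted over the list alone. With the compared groups alone 1 gene passed, and without the 2 widely spread arrays of these groups and 9 others 121 passed. Without ectoderm replicates 2, 4 and 5 the counts were 50, 164 and 141, and without otic replicates 3 and 4 they were 175 and 22.

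At E10.5, libraries labelled mandibular arch were compared with libraries labelled maxillary arch. Alx1 (probe set 10372145) was 16.0-fold higher in the libraries labelled mandibular, at 5.34 ± 0.26 (SD, n = 4) against 1.34 ± 1.48 (SD, n = 5), a difference of 4.00 ± 0.58 (SE, adjusted p = 4.9e-06). Sfn (probe set 10517067), a regulator of keratinocyte growth, was 9.10-fold lower (-3.19 ± 0.65, adjusted p = 0.0035). Hand2, which was higher in the mandibular arch at E9.5, was here 2.39-fold lower, at -0.20 ± 0.30 (SD, n = 4) against 1.05 ± 0.96 (SD, n = 5) with overlapping libraries (adjusted p = 0.044), and it did not pass without mandibular replicates 2, 3 or 4 (-1.19, -1.31 and -1.15), without maxillary replicates 1, 3 or 4 (-1.03, -0.99 and -1.30) after quantile normalization (-1.67, adjusted p = 0.062) or without the widely spread arrays (-1.55, adjusted p = 0.13). In all, 66.2% of the 154 genes rose and 52 fell, but after quantile normalization 73 rose and 124 fell.

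Surface ectoderm genes moved with this comparison (fry adjusted p = 0.000618), with 4 of 18 lower in the libraries labelled mandibular, 8 adjusted over the list alone, among them Perp by -3.12 and Krt14 by -2.89 on the log2 scale. Mesenchyme (fry adjusted p = 0.00593), frontonasal (adjusted p = 0.0047) and endothelial lists (adjusted p = 0.00633) moved up, with 1 of 15, 1 of 8 and 2 of 10 members higher, and 8, 1 and 3 adjusted over each list alone, where 1 mesenchyme gene was lower. The endothelial list did not pass without the widely spread arrays (adjusted p = 0.0513). The macrophage list moved up (adjusted p = 0.00686, adjusted p = 0.05 with an estimated correlation, adjusted p = 0.428 with array weights), with 1 of 8 higher, Cx3cr1 by 1.02, and 2 adjusted over the list alone. Its mean was 1.72 in mandibular replicate 3, 0.14 to 0.30 in the other 3 and -0.02 to 0.45 in the maxillary libraries. The difference of 0.46 was 0.08 without that library (adjusted p = 0.556), and the list did not pass without the widely spread arrays either (adjusted p = 0.824). Of 7 maxillary genes 1 fell, 2 adjusted over the list alone (adjusted p = 0.0362, adjusted p = 0.104 with an estimated correlation). That list did not pass without mandibular replicate 1 or 2 (adjusted p = 0.0641 and 0.149), maxillary replicate 4 or 5 (adjusted p = 0.0827 and 0.214) or the widely spread arrays (adjusted p = 0.109), or with the lower tail of each array, its 5th percentile, as a covariate (adjusted p = 0.0506). The mandibular, arch muscle, BMP and cartilage lists did not move (adjusted p = 0.309 to 0.975), with 1 of 8 mandibular genes, Hand2, lower, also 1 adjusted over the list alone. Array weights gave 729 genes, of which 334 rose and 395 fell, the compared groups alone 1, the lower tail as a covariate 289, and 74 passed without the 11 widely spread arrays. Without mandibular replicate 3 the count was 94, and without maxillary replicates 4 and 5 it was 92 and 274.

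The ectoderm of the arches at E10.5 was compared by its labels in the same way. Cldn7 (probe set 10377673), an epithelial claudin, was 29.7-fold lower in libraries labelled mandibular arch ectoderm, at -0.19 ± 0.27 (SD, n = 4) against 4.70 ± 0.73 (SD, n = 4) in those labelled maxillary arch ectoderm, a difference of -4.89 ± 0.98 (SE, adjusted p = 0.0021). Epcam, an epithelial adhesion protein, was 11.1-fold lower (adjusted p = 0.012). Hand2 was 4.86-fold higher, at 2.32 ± 0.98 (SD, n = 4) against 0.04 ± 0.19 (SD, n = 4), a difference of 2.28 ± 0.35 (SE, adjusted p = 3e-05). In all, 135 genes rose and 126 fell, and after quantile normalization 94 rose and 132 fell.

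Of 18 surface ectoderm genes 6 fell and 12 did not pass, 12 adjusted over the list alone (fry adjusted p = 6.4e-05). Pharyngeal arch genes moved up (fry adjusted p = 2.86e-09) with 7 of 13 higher, 11 adjusted over the list alone, among them Barx1 by 3.44 and Prrx1, a gene of limb and arch mesenchyme, by 2.53. Of 8 mandibular genes 3 rose, 5 adjusted over the list alone (fry adjusted p = 0.000913, adjusted p = 0.0515 without the widely spread arrays). Mesenchyme genes moved up as well (adjusted p = 0.00832, adjusted p = 0.0735 with an estimated correlation), with 3 of 15 higher, 4 adjusted over the list alone, as did the Hedgehog response list (adjusted p = 0.000673), with 1 of 5 higher, 3 adjusted over the list alone. The BMP, FGF and WNT lists did not move (adjusted p = 0.515 to 0.774), with 1 of 20 WNT genes lower, also 1 adjusted over the list alone. Of the libraries labelled mandibular arch ectoderm, replicates 1 and 3 correlated at 0.928 over genes, where the next of 193 pairs within groups reached 0.814, and with their mean as 1 library 126 genes rose and 50 fell. Without the widely spread arrays 76 rose and 196 fell. Array weights gave 332 higher and 529 lower genes, the lower tail as a covariate 299 and 417, and the compared groups alone 61 and 26. Without maxillary ectoderm replicates 1 and 4 the counts were 167 and 444.

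**Figure D2:**
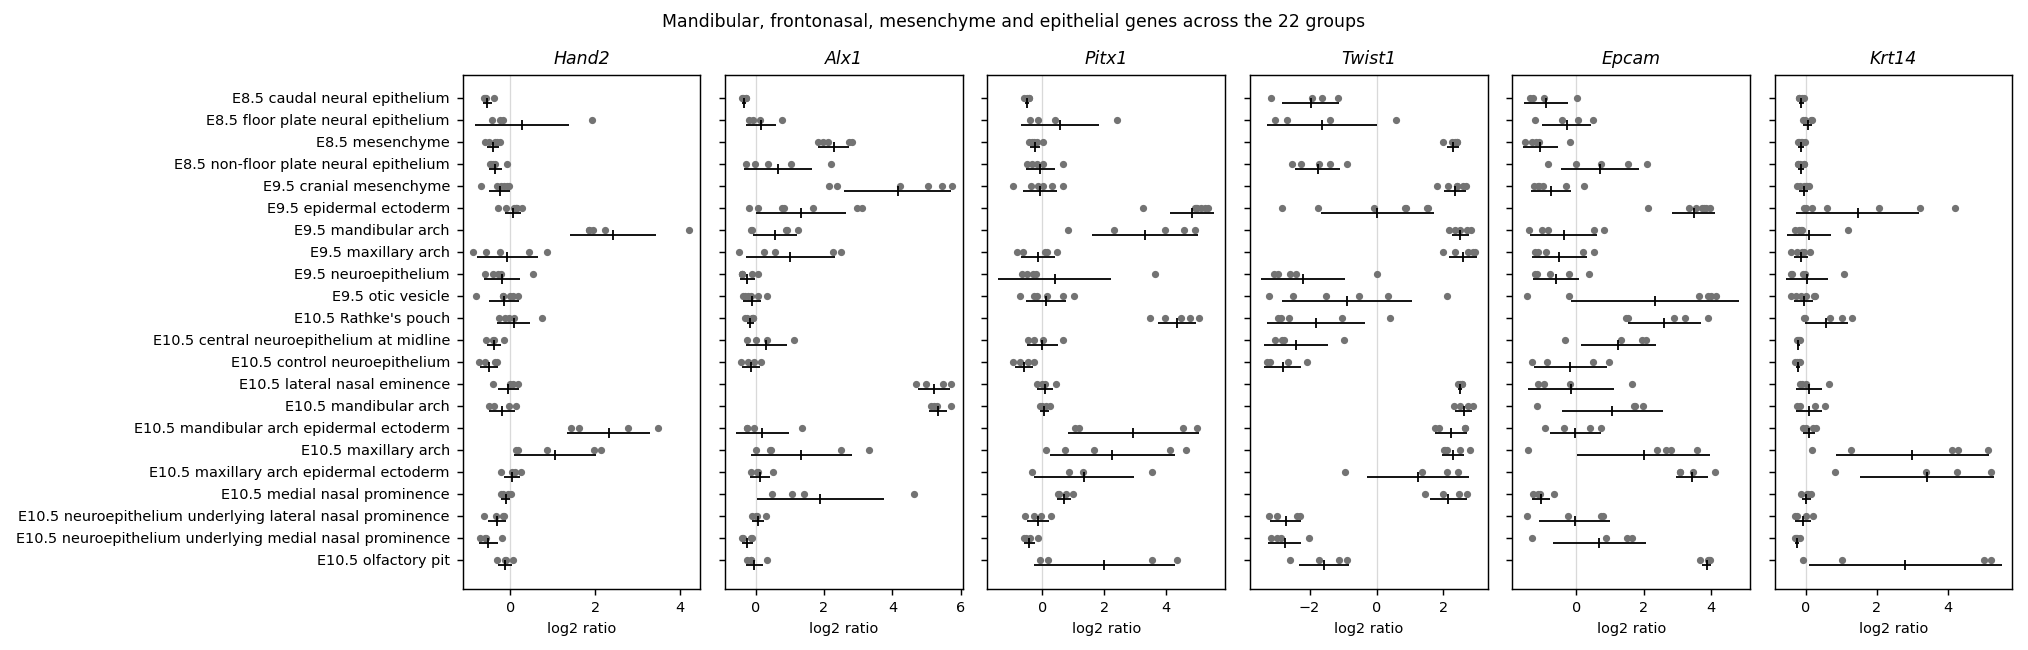
Log2 ratio (x axis) of Hand2, Alx1, Pitx1, Twist1, Epcam and Krt14 in the 22 groups (y axis), where points are libraries and the tick and bar are the mean ± SD. Hand2 averages 2.41 in E9.5 mandibular arch, 2.32 in libraries labelled E10.5 mandibular arch ectoderm and -0.20 in those labelled E10.5 mandibular arch, where Alx1 averages 5.34.

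At E10.5 the medial nasal prominence was compared with the lateral nasal eminence, the swellings on either side of the nasal pit. Alx1 was lower medially, at 1.89 ± 1.86 (SD, n = 4) against 5.21 ± 0.46 (SD, n = 4), a difference of -3.32 ± 0.61 (SE, adjusted p = 0.0016). Alx1 did not pass without the widely spread arrays (-2.92, adjusted p = 0.057). Tbx3 (probe set 10525016), a T-box repressor, was 2.87-fold higher medially (1.52 ± 0.27, adjusted p = 0.0012). In all, 12 genes rose and 11 fell, and after quantile normalization 27 rose and 16 fell.

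Of 8 frontonasal regulators 1 fell, Alx1, also 1 adjusted over the list alone, and the list moved down by 0.80 on average (fry adjusted p = 0.00229). Lateral replicate 3 stood apart, with a list mean of 2.30, against 0.79 to 1.04 in the other lateral and -0.02 to 0.95 in the medial libraries, and its 5th percentile was -0.31, against -2.17 to -1.38 in the other 3. Without it the difference was -0.45 (adjusted p = 0.109). The retinoic acid, FGF, WNT and Hedgehog response lists did not move (adjusted p = 0.0897 to 0.94). Array weights gave 45 higher and 57 lower genes, the lower tail as a covariate 40 and 95, omission of the widely spread arrays 37 genes and the compared groups alone 0 in limma, while 1759 genes had an unadjusted p under 0.05 in the fit over all groups. Without lateral replicates 2 and 3 the counts were 37 and 104, and without medial replicates 3 and 4 they were 115 and 114.

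Neuroepithelium under the nasal prominences at E10.5, medial and lateral together, was compared with control neuroepithelium. Rspo3 (probe set 10368495), an activator of WNT signalling, was 21.5-fold lower under the prominences, at 0.01 ± 0.26 (SD, n = 8) against 4.44 ± 2.12 (SD, n = 4), a difference of -4.43 ± 0.42 (SE, adjusted p = 5e-13). Olig3 (probe set 10361895), a transcription factor of dorsal neural tube, was 14.8-fold lower (-3.89 ± 0.19, adjusted p = 8.5e-29). Neurog2, a proneural gene, was 4.11-fold lower with overlapping libraries (adjusted p = 8.1e-08). Apela (probe set 10578950), a peptide hormone of the early embryo, was 20.1-fold higher (4.33 ± 0.68, adjusted p = 2e-05). Isl1 was 10.7-fold higher (adjusted p = 0.0063), but not with the lateral libraries alone (2.81, adjusted p = 0.24). WNT genes moved down (fry adjusted p = 6.4e-05) with 5 of 20 lower, 6 adjusted over the list alone, and BMP genes moved down (adjusted p = 0.0191) with 1 of 13 lower, Id3 at -1.27, and 3 adjusted over the list alone. The BMP list did not pass without control replicate 2 (adjusted p = 0.0709) or 1 (adjusted p = 0.242), where its mean difference went from -0.74 to -0.49.

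Neuronal differentiation genes went both ways, with 2 of 20 higher and 1 lower, 4 and 3 adjusted over the list alone, and the list did not move in 1 direction (adjusted p = 0.981). The forebrain and midbrain, boundary, FGF and Hox lists did not move (adjusted p = 0.584 to 0.872). In all, 10 genes rose and 49 fell, and with the compared groups alone 2 genes passed. For the 4 libraries under the medial prominence the titles name the lateral and the other labels the medial side, and without them 51 genes passed.

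The neuroepithelium under the medial and the lateral prominence differed in 35 genes, grouped by those other labels. Gpr50 (probe set 10600024), a receptor related to melatonin receptors, was 8.14-fold higher medially, at 3.08 ± 1.36 (SD, n = 4) against 0.06 ± 0.19 (SD, n = 4), a difference of 3.02 ± 0.55 (SE, adjusted p = 0.00099). Olig2 (probe set 10436823), a transcription factor of ventral progenitors, was 4.39-fold higher (2.13 ± 0.38, adjusted p = 0.00099) and did not pass after quantile normalization (1.71, adjusted p = 0.11). FGF genes moved up medially (adjusted p = 0.00842, adjusted p = 0.066 with an estimated correlation, adjusted p = 0.0664 after quantile normalization), with 1 of 14 higher, 4 adjusted over the list alone, but not without medial replicate 1 or 2 (adjusted p = 0.0765 and 0.103). The gene, Fgf15 (adjusted p = 0.0027), did not pass without lateral replicate 3 or 4 (adjusted p = 0.085 and 0.077), or after quantile normalization (adjusted p = 0.059). The forebrain and midbrain, WNT and BMP lists did not move (adjusted p = 0.765 to 0.87). All 35 genes were higher medially and limma called 0 lower, with 1543 genes at an unadjusted p under 0.05 in either direction, whereas after quantile normalization 7 rose and 3 fell. Array weights gave 125 genes and the compared groups alone 1, none of the 35, and without lateral replicate 1 or medial replicates 1 and 3 the counts were 76, 77 and 68.

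Neuroepithelium at the midline at E10.5 was compared with the same control. Pax6 was 37.5-fold lower at the midline, at -0.46 ± 0.14 (SD, n = 4) against 4.77 ± 0.18 (SD, n = 4), a difference of -5.23 ± 0.74 (SE, adjusted p = 1.3e-06). Rspo3 was 23.0-fold lower (adjusted p = 8.4e-11). Isl1 (probe set 10412335) was 17.7-fold higher (4.15 ± 0.84, adjusted p = 0.0021). Of 20 neuronal differentiation genes 2 rose and 2 fell, 2 and 4 adjusted over the list alone, and the list did not move in 1 direction (adjusted p = 0.778). Neurog2 was 8.35-fold lower (adjusted p = 3.6e-12).

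WNT genes moved down at the midline (fry adjusted p = 0.00196) with 3 of 20 lower, 5 lower and 1 higher adjusted over the list alone, but not without control replicate 1 (adjusted p = 0.0572). The arch muscle list moved up (adjusted p = 0.00762) with 2 of 10 higher, Isl1 and Msc, also 2 adjusted over the list alone. Of 11 floor plate genes 1 rose, Sulf1, an enzyme that edits heparan sulfate, at 4.07-fold (adjusted p = 9.8e-06), and 1 fell, Nkx2-2, at 2.45-fold with overlapping libraries (adjusted p = 0.0079), which did not pass without control replicate 1 (-0.80, adjusted p = 0.35) or 3 (-0.97, adjusted p = 0.19). When adjusted over the list alone 2 were higher and 1 was lower, and the list did not move (adjusted p = 0.582), nor did the Hedgehog response, forebrain and midbrain and boundary lists (adjusted p = 0.21 to 0.9). In all, 52 genes rose and 42 fell. With the compared groups alone 5 genes passed, and without midline replicate 3 there were 145.

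The olfactory pit, the invaginating nasal epithelium, was compared at E10.5 with the mean of the groups labelled arch ectoderm. Cldn3 (probe set 10526241), an epithelial claudin, was 11.3-fold higher in the pit, at 4.13 ± 0.23 (SD, n = 4) against 0.63 ± 1.14 (SD, n = 8), a difference of 3.50 ± 0.49 (SE, adjusted p = 8.5e-06). Barx1 was 8.07-fold lower (-3.01 ± 0.46, adjusted p = 1.6e-05). With the libraries labelled maxillary arch ectoderm alone as reference, Barx1 (-1.29, adjusted p = 0.32) did not pass. In all, 75 genes rose and 11 fell.

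Of 11 olfactory placode genes 3 rose and 8 did not pass, 5 adjusted over the list alone (fry adjusted p = 6.43e-06). Sox2, a progenitor factor, was 8.68-fold higher with overlapping libraries (adjusted p = 0.011) and did not pass without pit replicate 2 (2.96, adjusted p = 0.051) or 3 (2.83, adjusted p = 0.075), or against maxillary arch ectoderm alone (2.06, adjusted p = 0.28). Neuronal differentiation genes moved up (fry adjusted p = 0.000164) with 4 of 20 higher, 9 adjusted over the list alone. The pharyngeal arch (fry adjusted p = 0.000296), mesenchyme (adjusted p = 0.000623) and Hedgehog response lists (adjusted p = 0.00778) lay lower than the mean of both references, with 4 of 13, 4 of 15 and 0 of 5 genes called, 5, 6 and 2 adjusted over each list alone. None of these 3 lists passed against maxillary arch ectoderm alone (adjusted p = 0.934, 0.207 and 0.699). Of 18 surface ectoderm genes 1 rose, 5 adjusted over the list alone, and of 14 FGF genes 1 rose, also 1 adjusted over the list alone, but neither list moved (adjusted p = 0.0731 and 0.0836). The compared groups alone gave 12 genes, and the libraries labelled maxillary arch ectoderm as the single reference gave 137.

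Rathke's pouch, the oral ectoderm that becomes the anterior pituitary, was set against the same reference. Hesx1 was 25-fold higher in the pouch, at 4.69 ± 0.61 (SD, n = 5) against 0.05 ± 0.52 (SD, n = 8), a difference of 4.65 ± 0.48 (SE, adjusted p = 4.8e-11). Six6 (probe set 10396367), a homeobox gene of eye and pituitary, was 17.2-fold higher (4.10 ± 0.56, adjusted p = 6.6e-07). Cga, the shared subunit of pituitary glycoprotein hormones, was 4.07-fold higher (2.03, adjusted p = 0.00036), or 1.20 without pouch replicate 5 (adjusted p = 0.028). S100a6 (probe set 10493820), a calcium-binding protein, was 19.1-fold lower (-4.26 ± 0.63, adjusted p = 3.4e-06). Of 11 pituitary placode genes 6 rose and 5 did not pass, 7 adjusted over the list alone (fry adjusted p = 8.91e-18). In all, 110 genes rose and 79 fell.

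Forebrain and midbrain regulators moved up in the pouch (fry adjusted p = 3.55e-06) with 3 of 11 higher, among them Hesx1 and Six6, and 4 adjusted over the list alone, as did the neural epithelium list (adjusted p = 0.00358, adjusted p = 0.0765 without the widely spread arrays) with 1 of 15 higher, also 1 adjusted over the list alone. Pharyngeal arch (fry adjusted p = 0.000135) and mesenchyme genes (adjusted p = 0.00124) lay lower than the mean of both references, with 4 of 13 and 3 of 15 lower, 5 and 6 adjusted over each list alone, but not lower than maxillary arch ectoderm alone (adjusted p = 0.958 and 0.328). Of 18 surface ectoderm genes 1 rose, 4 adjusted over the list alone, and this list (adjusted p = 0.295) and the pharyngeal endoderm list (adjusted p = 0.282, adjusted p = 0.0306 against maxillary arch ectoderm alone), with 1 of 11 higher, did not move. Quantile normalization gave 62 genes, the compared groups alone 18, the widely spread arrays left out 103 and the libraries labelled maxillary arch ectoderm as the single reference 137 higher and 188 lower. Without mandibular arch ectoderm replicates 2 and 4 the counts were 115 and 118, and without pouch replicates 2 and 3 they were 108 and 709.

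Libraries labelled mandibular arch were compared between E10.5 and E9.5, a direction that rests on labels which the markers of the E10.5 group go against. Barx1 was 27.1-fold lower at E10.5, at 0.31 ± 1.65 (SD, n = 4) against 5.07 ± 0.41 (SD, n = 5), a difference of -4.76 ± 0.50 (SE, adjusted p = 7.8e-11). Hand2 was 6.14-fold lower (adjusted p = 8.7e-08). Alx1 was 27.5-fold higher, at 5.34 ± 0.26 (SD, n = 4), beside 5.21 in E10.5 lateral nasal eminence, against 0.56 ± 0.64 (SD, n = 5), a difference of 4.78 ± 0.58 (SE, adjusted p = 1.5e-08). Pax9 (probe set 10395849), a paired box gene of jaw and tooth mesenchyme, was 5.75-fold higher (2.52 ± 0.19, adjusted p = 3e-18). In all, 247 genes rose and 1144 fell, but after quantile normalization 501 rose and 581 fell, and without the 2 widely spread arrays of the E10.5 group and 9 others 59 rose and 37 fell.

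Pharyngeal arch genes moved down (fry adjusted p = 7.87e-07) with 5 of 13 lower, 6 lower and 1 higher adjusted over the list alone, as did the mandibular list (adjusted p = 5.71e-08) with 5 of 8 lower, 6 lower and 1 higher adjusted over the list alone. Frontonasal regulators moved up (fry adjusted p = 2.31e-07) with 3 of 8 higher, also 3 adjusted over the list alone, and macrophage genes moved up (adjusted p = 0.000244) with 4 of 8 higher, 5 adjusted over the list alone. E10.5 replicate 3 stood apart with a macrophage mean of 1.72, against 0.14 to 0.30 in the other 3 and -0.14 to 0.14 at E9.5. The shift of 0.62 was 0.25 without it (adjusted p = 0.0594), and the list did not pass without the widely spread arrays (adjusted p = 0.239). Cell cycle genes moved down (adjusted p = 0.0142, adjusted p = 0.369 with an estimated correlation) with 4 of 15 lower, 8 adjusted over the list alone, as did endothelial genes (adjusted p = 0.000379, adjusted p = 0.16 with an estimated correlation) with 2 of 10 lower, 7 adjusted over the list alone, and genes of hypoxia and glycolysis (adjusted p = 1.5e-05, adjusted p = 0.0754 with an estimated correlation) with 5 of 11 lower, 6 adjusted over the list alone. In the widely spread E10.5 replicates 1 and 3, with a 5th percentile of -2.05 and -1.72, the list means were -0.92 and -0.76 for cell cycle, 0.31 and 0.63 for endothelial and -1.03 and -1.19 for hypoxia genes. In replicates 2 and 4, at -0.45 and -0.32, they were -0.19 and 0.003, 0.93 and 1.06, and -0.34 and -0.23. The cell cycle list did not pass without the widely spread arrays (adjusted p = 0.249), E9.5 replicate 2 (adjusted p = 0.0707) or E10.5 replicates 1 or 3 (adjusted p = 0.0665 and 0.0615). Of 13 cartilage genes Col9a1, a cartilage collagen, was 4.01-fold lower (adjusted p = 0.00013) and 1 rose, with 1 higher and 1 lower adjusted over the list alone. The cartilage, mesenchyme, neural crest and erythroid lists did not move (adjusted p = 0.337 to 0.812), with 1 of 15 mesenchyme genes higher, and 1 higher and 1 lower adjusted over the list alone. The compared groups alone gave 27 genes, and the lower tail as a covariate 444. Without E9.5 replicates 2 and 5 the counts were 308 and 506, and without E10.5 replicates 1, 3 and 4 they were 334, 360 and 2090.

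The same comparison of libraries labelled maxillary arch gave 335 genes that rose and 1372 that fell, but after quantile normalization 535 rose and 370 fell. Krt14 (probe set 10391052), a keratin of basal epidermis, was 8.69-fold higher at E10.5, at 2.99 ± 2.14 (SD, n = 5) against -0.13 ± 0.20 (SD, n = 5), a difference of 3.12 ± 0.61 (SE, adjusted p = 0.00089). Foxc1 (probe set 10404407) was 11.7-fold lower (-3.54 ± 0.57, adjusted p = 4.9e-05). Surface ectoderm genes moved up (fry adjusted p = 1.28e-05) with 7 of 18 higher, 14 adjusted over the list alone, among them Epcam by 2.51, with a list mean of -0.24 in E10.5 replicate 5 and 0.85 to 2.96 in the other 4, and endothelial genes moved down (adjusted p = 4.54e-08) with 9 of 10 lower, also 9 adjusted over the list alone.

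Mesenchyme genes moved down (adjusted p = 0.000173, adjusted p = 0.169 with an estimated correlation) with 4 of 15 lower, 7 adjusted over the list alone. Cell cycle genes moved down (adjusted p = 0.00497, adjusted p = 0.307 with an estimated correlation) with 7 of 15 lower, 10 lower and 1 higher adjusted over the list alone, among them Mcm2 at 4.96-fold (adjusted p = 0.0054) with overlapping libraries. Genes of hypoxia and glycolysis moved down (adjusted p = 0.00509, adjusted p = 0.36 with an estimated correlation) with 2 of 11 lower, 5 adjusted over the list alone, but not without E9.5 replicate 2 (adjusted p = 0.0508). In E9.5 replicates 4 and 5, with a 5th percentile of -1.33 and -1.01, the means were -0.21 and -0.35 for cell cycle, -0.37 and -0.24 for hypoxia and 1.19 and 1.41 for mesenchyme genes, against 0.79 to 1.34, 0.53 to 0.94 and 1.59 to 2.23 in replicates 1 to 3, at -0.43 to -0.35. Where the 5th percentile was -0.64 and -0.72, in E10.5 replicates 1 and 3, the means were -0.09 and -0.03 for cell cycle and 0.12 and -0.04 for hypoxia genes. In replicates 2, 4 and 5, at -1.37, -2.05 and -1.90, they were -0.83, -1.13 and -1.46, and -0.54, -0.81 and -0.88. Of 13 pharyngeal arch genes 2 rose and 2 fell, 3 and 3 adjusted over the list alone, and of 13 cartilage genes 2 fell, with 1 higher and 2 lower adjusted over the list alone. The pharyngeal arch, cartilage, neural crest and erythroid lists did not move (adjusted p = 0.12 to 0.872), with 1 of 9 neural crest and 1 of 8 erythroid genes lower, 1 and 2 adjusted over each list alone. Array weights gave 4913 genes, the compared groups alone 34, the widely spread arrays left out 1029 and the lower tail as a covariate 642. Without E9.5 replicates 1 to 5 the counts were 543, 357, 744, 3713 and 2965, and without E10.5 replicates 2, 4 and 5 they were 1018, 634 and 1096.

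A test of the difference asked whether mandibular and maxillary arch differed otherwise at E10.5 than at E9.5, by the labels. The difference rose for Alx1 by 4.46 ± 0.80 (SE, adjusted p = 0.0011) and for Pax9 by 2.86 ± 0.26 (SE, adjusted p = 7.9e-14), and fell for Pitx1, at -5.67 ± 1.00 (SE, adjusted p = 0.0011), and Cxcl14, a chemokine of epithelia, at -4.27 ± 0.85 (SE, adjusted p = 0.007). In all, 8 genes rose and 5 fell, and after quantile normalization 8 rose and 15 fell. Array weights gave 110 higher and 128 lower genes, the compared groups alone 1, the widely spread arrays left out 31, and the lower tail as a covariate 23. Without E9.5 maxillary replicates 3 and 4 the counts were 20 and 20, without E10.5 mandibular replicate 1 there were 21, and without E10.5 maxillary replicates 4 and 5 there were 26 and 38.

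A second test asked whether the arches at E10.5 differed otherwise than the ectoderm labelled to cover them. The mandibular minus maxillary difference was lower in arch than in ectoderm for Barx1, by -5.08 ± 0.73 (SE, adjusted p = 7.1e-06), and Hand2, by -3.54 ± 0.49 (SE, adjusted p = 4.1e-06). It was higher for Gata2, a GATA factor, by 1.94 ± 0.30 (SE, adjusted p = 4e-05), and Pax9, by 1.70 ± 0.27 (SE, adjusted p = 6.1e-05). Pax9 did not pass without the widely spread arrays (1.02, adjusted p = 0.18). In all, 6 genes rose and 6 fell, and after quantile normalization 2 rose and 6 fell. Array weights gave 94 genes, the lower tail as a covariate 13 higher and 26 lower, the widely spread arrays left out 20 higher and 7 lower and the compared groups alone 0 in limma, while 1264 genes had an unadjusted p under 0.05 in the fit over all groups. Without mandibular arch replicate 4 there were 20, without mandibular ectoderm replicate 4 there were 19, and without maxillary ectoderm replicate 3 there were 7.

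Enriched genes passed at 2-fold or more against each other region of their stage. At E8.5 this gave 196 genes: 110 in mesenchyme, 73 in caudal, 7 in floor plate and 6 in non-floor plate neural epithelium. At E9.5 there were 63: 33 in neuroepithelium, 13 in otic vesicle, 8 in cranial mesenchyme, 5 in epidermal ectoderm, 4 in mandibular arch and 0 by limma in maxillary arch. There 692 genes differed from mandibular arch at an unadjusted p under 0.05, below chance. E9.5 neuroepithelium was uneven, with forebrain and midbrain means of 2.01 and 1.94 in replicates 1 and 2 and 0.09 to 0.42 in the others. The others had boundary means of 1.18 to 2.05, against -0.32 and 0.45. At E10.5 there were 46, of which control neuroepithelium had 12, olfactory pit 9, Rathke's pouch 7, midline neuroepithelium 6, neuroepithelium under the medial prominence 5 and libraries labelled mandibular arch 4. Olig3 was at least 13.5-fold higher in control neuroepithelium, Hesx1 19.6-fold in Rathke's pouch, and Sulf1 4.07-fold at the midline. With array weights there were 129 at E9.5 and 70 at E10.5.

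Over all 32 lists and 16 comparisons, 79 of 512 pairs moved, 42 up and 37 down, and 56 moved by camera with an estimated correlation. The Hox (smallest adjusted p = 0.122), caudal progenitor (0.138), cardiac (0.235) and pharyngeal endoderm lists (0.0538) moved in no comparison.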

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

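The divisions of the samples were planned before results were seen, while tests on the arch libraries and the direction of change over time were chosen after. Among 590 sets of 1 named gene in 1 group, a library stood apart from all others of its group in 58 sets (9.8%), in 43 libraries, where the rule by its construction gives about 1 in 20 by chance. Values are log2 distances to the median of the others, negative where the library lay below. For Hbb-bh1 and Hbb-y nearly all of the others lay at the smallest ratio, which sets these distances. At E8.5, for non-floor plate neural epithelium it was Foxc2 by 1.48, Sparcl1 by 1.07, Esam by -0.30 and Hbb-y by 2.00 in replicate 1, Lum by 0.68 in replicate 2, Foxc1 by 1.27 in replicate 3, and Foxa2 by 0.85, Tfap2b by 1.45 and Cldn10 by 1.97 in replicate 5. For floor plate it was Foxf1 by 3.21, Lum by 4.24 and Hapln1 by 0.36 in replicate 4, Foxc2 by 1.60 in replicate 3, Hbb-bh1 by 0.09 in replicate 1 and Hbb-y by 0.84 in replicate 2. For mesenchyme it was Sparcl1 by -0.97 in replicate 2. For caudal it was Hbb-bh1 by 1.36 in replicate 4, and Hbb-y by 2.01 and Aldh1a2 by 1.49 in replicate 3.

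At E9.5, in mandibular arch it was Lhx8 by -3.02 in replicate 5, and Pax3 by -0.16 and Hand2 by 2.33 in replicate 6. In maxillary arch it was Meis2 by -1.91 and S100a11 by -2.73 in replicate 4. In cranial mesenchyme it was Meis2 by 2.18 in replicate 2 and Dlx5 by 2.29 in replicate 1. In epidermal ectoderm it was Pitx1 by -1.81 in replicate 6 and Sox10 by 0.59 in replicate 7.

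At E10.5, in maxillary arch it was Ccdc84 by 0.73 in replicate 2, S100a11 by -1.87 in replicate 5, Fermt2 by -0.32 in replicate 2 and Hand1 by 2.50 in replicate 1. In mandibular arch it was Ecscr by 1.08 in replicate 3. In mandibular arch ectoderm it was Cldn5 by 1.21 in replicate 4 and Neurod1 by 0.23 in replicate 2. Among lateral nasal eminence libraries this was Gsc by -1.68 in replicate 3, Hpgd by 3.66 in replicate 3 and Crabp2 by 0.54 in replicate 3. Among medial nasal prominence libraries this was Cxcl13 by -0.32 in replicate 1 and Crabp2 by -2.93 in replicate 2. Among control neuroepithelium libraries this was Isl1 by 0.45 in replicate 3, Pou3f3 by -0.32 in replicate 4 and Rai2 by 2.06 in replicate 2. Among neuroepithelium under lateral nasal prominence libraries this was Upp1 by 0.98 in replicate 1, Gpr50 by 0.38 in replicate 3 and Frmd5 by 0.98 in replicate 1. Among neuroepithelium under medial nasal prominence libraries this was Otx2 by 0.55 in replicate 3. Among midline neuroepithelium libraries this was Tal2 by -1.25 in replicate 2, Pax6 by 0.28 in replicate 1 and Lix1 by -0.63 in replicate 3. Among olfactory pit libraries this was Tubb3 by -0.91 in replicate 4 and Gadd45g by 1.99 in replicate 1. Among maxillary arch ectoderm libraries this was Cldn3 by 1.66 in replicate 4, Cga by 0.23 in replicate 3 and S100a6 by -1.84 in replicate 4. Among Rathke's pouch libraries this was Hesx1 by -1.31 in replicate 4, Cldn10 by -3.52 in replicate 2 and Cga by 4.20 in replicate 5.

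Differences between mandibular and maxillary arch changed between the stages, by a test of the change, for Pantr1 by 6.01, Alx1 by 4.46, Pax9 by 2.86, Dapl1 by -6.43, Pitx1 by -5.67 and Cxcl14 by -4.27. They also differed between arch and arch ectoderm at E10.5 for Alx1 by 3.93, Gata2 by 1.94, Pax9 by 1.70, Barx1 by -5.08, Kazald1 by -3.98 and Hand2 by -3.54.

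Libraries labelled E10.5 mandibular arch ectoderm were low in surface ectoderm genes and high in mandibular and mesenchyme genes. Capture of mesenchyme with 25% or more ectoderm would leave ectoderm genes at most 4-fold lower than in maxillary arch ectoderm. The median over 9 genes picked as high in the latter was -3.03 ± 0.33 (SE over genes) in log2. The choice lowers the median, which cannot decide. An exchange of labels with the mandibular arch group needs ectoderm genes there, and the mean of the 18 list genes was 0.40 ± 0.22 (SE over libraries) higher, which argues against it. An exchange with the maxillary arch group, whose mean was 1.61 ± 0.58 (SE) higher, cannot be told apart from a capture of less ectoderm, since the mandibular list of these libraries lay 1.04 ± 0.51 (SE) above E9.5 maxillary arch, through replicates 2 and 4 at 1.91 and 2.37, while replicates 1 and 3 at 0.76 and 0.64 lay within its range. That range reaches so high only through E9.5 maxillary replicate 3 at 1.23, with the other libraries at -0.30 to 0.56. A difference between the arches themselves stays open and was not tested.

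Of 5 libraries labelled E10.5 maxillary arch, 4 were high in surface ectoderm genes, at 0.85 to 2.96, and replicate 5 was not, at -0.24, with a group mean 1.47 ± 0.62 (SE) above E9.5 maxillary arch. Capture of mesenchyme together with ectoderm needs mesenchyme genes above those of maxillary arch ectoderm, and the mean over 15 genes and all 5 libraries was 0.50 ± 0.28 (SE) higher, or 0.30 ± 0.20 (SE) without replicate 1. Only replicates 1 and 5, at 1.49 and 0.79, lay above the ectoderm libraries (-0.20 to 0.57), and replicates 2 to 4 lay among them at 0.24 to 0.43. A change of the tissue with stage was not tested, and both explanations stay open.

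More genes were lower than higher at E10.5 in both arches. Arrays differed in spread, with an SD of the log2 ratios from 0.40 to 1.35. With the lower tail of each array as a covariate, 75.2% of 444 genes in the mandibular and 76.0% of 642 in the maxillary arch were lower, after quantile normalization 53.7% and 40.9%, and without the widely spread arrays 38.5% and 74.6%. The lower tail of the arrays and a change with stage therefore cannot be told apart, and for the mandibular arch the E10.5 labels stay open too.

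Divisions of the same samples into groups of the same sizes, the labelled one included, were counted where they called as many genes, with up to 100 drawn, and the labelled count is given against the highest other. Chance could be excluded, unadjusted for multiple tests, for E8.5 mesenchyme 1 of 100 (478 against 279), caudal 1 of 100 (283 against 169), E10.5 arch ectoderm 1 of 35 (261 against 45), olfactory pit 3 of 100 (86 against 147), regions at E8.5 1 of 100 (196 against 72), regions at E9.5 1 of 100 (63 against 35) and regions at E10.5 1 of 100 (46 against 14). In the full set it was excluded narrowly for mandibular arch over time 1 of 100 (1391 against 1370), and for E9.5 arches and cranial mesenchyme 4 of 100 (186 against 2824). With single libraries left out these counts were 308 to 2090 and 80 to 927, so both rest on single libraries. Without the widely spread arrays the first was 96. No divisions were drawn with libraries left out, or with the similar arch ectoderm arrays (r = 0.928) as their mean, where 176 genes passed. For arch ectoderm the test takes them as independent. Chance could not be excluded for floor plate 6 of 100 (36 against 40), E9.5 mandibular and maxillary arch 23 of 100 (14 against 2344), otic vesicle 12 of 100 (78 against 1834), E10.5 mandibular and maxillary arch 5 of 100 (154 against 858), nasal prominences 12 of 35 (23 against 473), neuroepithelium under the prominences 10 of 100 (59 against 264), neuroepithelium under medial and lateral prominence 3 of 35 (35 against 155), midline 2 of 35 (94 against 352), Rathke's pouch 5 of 100 (189 against 1420), maxillary arch over time 7 of 100 (1707 against 3736), change of the arch difference with stage 7 of 100 (13 against 6161) and arch difference against ectoderm 18 of 100 (12 against 407). Where other divisions called several times the labelled count, as in the arches and cranial mesenchyme at 2824 and the change of the arch difference at 6161, this points to a structure of the samples beside their groups.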

How the results depend on the processing

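Alternatives listed above as added were chosen after the data were seen. Values of named genes that kept their direction and side of the threshold numbered 270 with a variance trend and robust prior, 268 with the mean of probe sets, 262 with the lower tail as a covariate, 255 with array weights and 238 after quantile normalization. In the same order 2, 4, 8, 11 and 34 no longer passed. Without the widely spread arrays 51 no longer passed, with maxillary arch ectoderm alone 11, with similar arrays as their mean 8 and without the samples under the medial prominence 6. With the further sample as mandibular arch or as ectoderm 3 each no longer passed. When single libraries were left out, 2689 values were kept and 339 no longer passed. With the compared groups alone 170 no longer passed, and 179 with the replicate block, where these groups alone estimate the spread. The direction turned for Lum in floor plate, which ranged from -0.10 without floor plate replicate 4 to 1.31, and for Cldn6 between the E9.5 arches, at 0.06 with the further sample as mandibular arch. Neither was called. The filter on dim genes was not run, and no background signal was used. The cause of losses above and changes below was not tested.

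These counts of genes moved by more than 1.5 times. Quantile normalization gave 159 for caudal neural epithelium, 5 for the E9.5 arches, 43 for the nasal prominences and 10 for neuroepithelium under medial and lateral prominence. It gave 62 for Rathke's pouch, 905 for maxillary arch over time and 23 for the change of the arch difference with stage. Array weights gave 99 for floor plate, 896 for mesenchyme, 714 for caudal, 3495 for arches and cranial mesenchyme, and 85 and 729 for the E9.5 and E10.5 arches. They gave 861 for arch ectoderm, about 1.0e+02 for the nasal prominences, 125 for medial and lateral neuroepithelium and 4913 for maxillary arch over time. For the change of the arch difference with stage and against ectoderm they gave 238 and 94, and for regions at E9.5 and E10.5 129 and 70. The compared groups alone gave 1 for floor plate, 76 for caudal, 12 for arches and cranial mesenchyme, 1 for otic vesicle, 1 for the E10.5 arches and 87 for arch ectoderm. They gave 2 for neuroepithelium under the prominences, 1 for its medial and lateral parts, 5 for midline, 12 for olfactory pit and 18 for Rathke's pouch. For mandibular and maxillary arch over time they gave 27 and 34, and for the change with stage 1. The further sample counted as mandibular arch gave 7 for the E9.5 arches. Without otic libraries 3 and 5 there were 190 for otic vesicle. Without the widely spread arrays there were 121 for otic vesicle, 74 for the E10.5 arches, 37 for the nasal prominences and 103 for Rathke's pouch. The arches over time had 96 and 1029, and the changes of the arch difference 31 and 27. The lower tail as a covariate gave 289 for the E10.5 arches, 716 for arch ectoderm, 135 for the nasal prominences, 444 and 642 for the arches over time, and 23 and 39 for the changes of the arch difference. Maxillary arch ectoderm alone gave 137 for olfactory pit and 325 for Rathke's pouch. Camera with the preset correlation called 136 list shifts.

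With single libraries left out the counts ranged from 26 to 78 for floor plate, 391 to 485 for mesenchyme, 217 to 278 for caudal, 80 to 927 for arches and cranial mesenchyme, 4 to 23 for the E9.5 arches and 22 to 175 for otic vesicle. At E10.5 they ranged from 92 to 274 for the arches, 167 to 444 for arch ectoderm, 19 to 115 for the nasal prominences, 41 to 85 for neuroepithelium under the prominences and 30 to 77 for its medial and lateral parts. They ranged from 82 to 145 for midline, 62 to 98 for olfactory pit and 108 to 709 for Rathke's pouch. For mandibular and maxillary arch over time they were 308 to 2090 and 357 to 3713, and for the changes of the arch difference 10 to 38 and 7 to 20. Regions had 168 to 204, 52 to 85 and 39 to 56 at the 3 stages. The list shifts numbered 74 to 83. Of the 79, 24 ended with some single library left out (adjusted p = 0.0502 to 0.556), and for 14 any of 3 or more libraries did so. Among the 14 were maxillary genes between the E10.5 arches and cell cycle genes in mandibular arch over time. The others are only named here, as Hedgehog response and olfactory placode in mesenchyme, olfactory placode in floor plate, maxillary in caudal and in olfactory pit, cartilage in otic vesicle, pharyngeal arch between the nasal prominences, arch muscle under the prominences, pituitary placode in olfactory pit, mandibular and retinoic acid in Rathke's pouch and WNT in maxillary arch over time.

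In 0 of the 15 comparisons with pairs of the same number did every pair deviate together at r over 0.1, so the numbers were not taken to pair the libraries. In the arches and cranial mesenchyme 8 of 10 pairs did (median 0.19, other numbers -0.06), and in maxillary arch over time 4 of 5 (0.22, others -0.10). In 0 of 15 did every library correlate best with its own number, with 10 of 20 and 3 of 10 in these comparisons. Noisy pairs can miss this rule, so pairing stays open. With the replicate number as a block, 274 genes passed for mesenchyme, 5 for caudal, 14 for arches and cranial mesenchyme, 2 for otic vesicle, 16 for arch ectoderm, 1 for midline, 3 for olfactory pit, 12 for Rathke's pouch and 27 for maxillary arch over time. Limma called 0 with the block for floor plate, the E9.5 and E10.5 arches, the nasal prominences, mandibular arch over time and the changes of the arch difference with stage and against ectoderm. In the fit over all groups 905, 692, 2071, 1759, 5045, 943 and 1264 genes had an unadjusted p under 0.05 there, with 905, 692 and 943 below chance. Without the block limma also called 0 for the E9.5 arches, the nasal prominences and the change against ectoderm. Where the samples under the medial prominence enter, no paired analysis was possible, as they share fewer than 2 numbers with the groups beside them. The lateral and control groups alone gave 0 genes in limma with and without the block, with 1063 and 1152 at an unadjusted p under 0.05, near the chance share.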

Other observations

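All values in this part come from tests chosen after the data were seen. Embryonic globins were lowest at the first stage. Hbb-y had a median of -6.64 over 18 libraries at E8.5, where 10 lay at the smallest ratio of the table, against 0.08 over 34 at E9.5 and 0.16 over 50 at E10.5. Hbb-bh1 had medians of -6.60, 0.06 and 0.44, and Hba-x of -6.05, 0.07 and 0.11. The ranges overlapped, as Hbb-y reached -1.12 at E8.5 and lay at -5.06 in an E9.5 library. All regions are pooled in these medians, and stage was not tested for these genes.

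Group means at E10.5, less the mean over groups of the stage, were correlated with those at E9.5 across 331 genes of the lists, which are not independent replicates. The libraries labelled E10.5 mandibular arch ectoderm were nearest to E9.5 mandibular arch (r = 0.69). Those labelled E10.5 mandibular arch were nearest to E9.5 cranial mesenchyme (0.49), with 0.38 for E9.5 mandibular arch. Libraries labelled E10.5 maxillary arch were nearest to epidermal ectoderm at 0.29, against 0.09 with E9.5 maxillary arch. Olfactory pit (0.73) and Rathke's pouch (0.61) were nearest to epidermal ectoderm too.

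The E9.5 sample whose labels name both mandibular arch and epidermal ectoderm had Barx1 at 4.36, Pitx1 at 2.37, Hand2 at 0.41, Epcam at 2.13 and Cldn6 at 3.89. Its mean was 1.42 over surface ectoderm genes and 1.37 over mesenchyme genes.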
